A study of Homo sapiens with 16 samples.

How the data were processed

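RNA sequencing of A549 and H358 cells was analysed from the gene counts that the authors deposited in 1 table of 56269 genes and 16 libraries. Per the labels, RNA was extracted with RNeasy or RNAprep kits, ribosomal RNA was removed with Ribo-Zero Gold, and libraries were made by a dUTP stranded protocol. The labels name cutadapt, STAR and HTSeq and the hg38 genome for making the counts; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. All columns of the table belonged to a sample (0 columns without one). Groups came from the labels: control siRNA and EML4 siRNAs 34 and 36 in each line, and a control and EML4 overexpression in H358, with 2 libraries in each of 8 groups. The chi-square per gene between the 2 libraries of a group ran from 1.97 in the overexpression control to 10.5 in the A549 control, so no library was counted as a copy of another.

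Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20135. Counts were scaled by TMM and fitted in 1 model with a mean for each group, with 8 residual degrees of freedom, a common biological coefficient of variation of 4.78% and a prior of 30 degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood F test and the Benjamini-Hochberg adjustment over all genes tested, at 0.05. Knockdown was the mean of the 2 EML4 siRNAs against the control siRNA of the line; each siRNA alone, the siRNAs against each other (34 minus 36), overexpression against its control, and the difference of the knockdown effect between the lines (A549 minus H358) were tested too. A second model with a common knockdown effect was fitted to the 12 siRNA libraries. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with GENCODE release 29 for gene positions and 3′ UTRs. The standard error of a fold change is its absolute value divided by the square root of F.

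37 gene lists with 928 symbols, of which 908 matched the table, were fixed before the data were examined, as were the comparisons, the design, the rule for naming genes and the alternatives, except where a later choice is stated. A member was measured if it passed the filter and had counts in the groups compared. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, and again with an estimated correlation. These tests took all members that passed the filter, also those at 0 in the groups compared. For interferon-stimulated genes in H358 knockdown they took 30 members, of which 25 were measured. Named genes were the 10 rising and 10 falling furthest in each main comparison among those past the threshold at 5 CPM or more, with each treated library beyond both controls and both siRNAs called in the same direction. Up to 2 rising and 2 falling members were named per list, 10 per overlap by the weaker of the 2 tests, and 5 per direction for differences between siRNAs. Symbols that are only clone names were counted and not named. VIM, TNN, ANTXR1, FN1 in A549, TUBA1B and the other symbols given as listed at 0 fell outside this rule and were chosen after their values were seen. XIST, TSIX and genes of chromosome Y were left out of the named genes and of all tables. Some genes and 2 gene lists are not reported here, and they remain in the totals.

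Depth ran from 20918670 to 34307728 counts per library. Simulated counts had 1 dispersion per gene, estimated over all 16 libraries and used for every group, although the real groups differed in spread. Changes were placed only in genes at 5 CPM or more in the control, and in far fewer genes than were called in the data. The shares below describe that setting and may not hold for groups that vary more, such as the A549 control. Of genes changed 1.5-fold, 97.9%, 99% and 87.7% were called for A549 knockdown, H358 knockdown and overexpression. Of those changed 2-fold, 100%, 100% and 97.9% were called, and 5.71%, 3.4% and 7.5% of all calls were false. Alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom, no low-count filter, a stricter filter of 5 CPM in 2 libraries, a replicate block, each experiment fitted alone, a 2-fold limit, the rotation test fry for lists, and leaving out each library in turn. A group left with 1 library was assumed to vary like the other groups. Words of 7 bases (16384) in annotated 3′ UTRs were related to fold changes at a mean of 10 CPM or more, with UTR length and GC content adjusted for, and compared with 200 permutations of the fold changes, for which 0.005 is the smallest p possible. GACGTA, of 6 bases, was followed as the core of the strongest words. Control and EML4 siRNA libraries were also split within each line in 100 of 225 possible ways.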

Results

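RNA was sequenced from A549 and H358, established human lung cancer cell lines, in 16 libraries that formed 8 groups of 2. In each line 1 group received a control siRNA and 2 groups received siRNAs numbered 34 and 36 against EML4, which encodes a protein that binds microtubules. H358 had 2 more groups, with EML4 overexpressed and with its own control. The submitters asked how EML4 acts in metastasis, within a series on RNA methylation in lung adenocarcinoma, and the comparisons gave the genes whose RNA changed when EML4 was lowered or raised. Total counts per library ran from 20918670 to 34307728, and 20135 of the 56269 listed genes were tested. Of 858 list members tested, 30 were listed at 0 in all 12 siRNA libraries and could not be followed there. Levels are means ± SD of counts scaled to library size (CPM) with n = 2 libraries per group. Values in brackets after a gene are log2 fold changes, and "rose" and "fell" are used of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

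EML4 (chromosome 2, 42169350 to 42332548, plus strand, hg38) was lowered by both siRNAs in both lines. In A549 it lay at 212 ± 4.8 CPM with the control siRNA, 33.1 ± 2.1 with siRNA 34 and 38.9 ± 1.1 with siRNA 36. In H358 the levels were 194 ± 7.1, 62.9 ± 1.5 and 47.3 ± 1.2 CPM. Averaged over the siRNAs, 16.9% of the control level was left in A549 (-2.57, SE 0.042) and 28.1% in H358 (-1.83, SE 0.04), and the effect differed between the lines (-0.74, adjusted p = 5.9e-12 in edgeR). Overexpression raised EML4 39.1-fold in H358, from 123 ± 5.1 to 4790 ± 95 CPM. The siRNAs differed from each other in H358, with more EML4 left by siRNA 34 (0.41, adjusted p = 1.5e-06 in edgeR). In A549 siRNA 34 left less (-0.24, adjusted p = 0.0074), a call lost without siEML4-34 replicate 2 (adjusted p = 0.21) or siEML4-36 replicate 1 (adjusted p = 0.14).

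**Figure D1:**
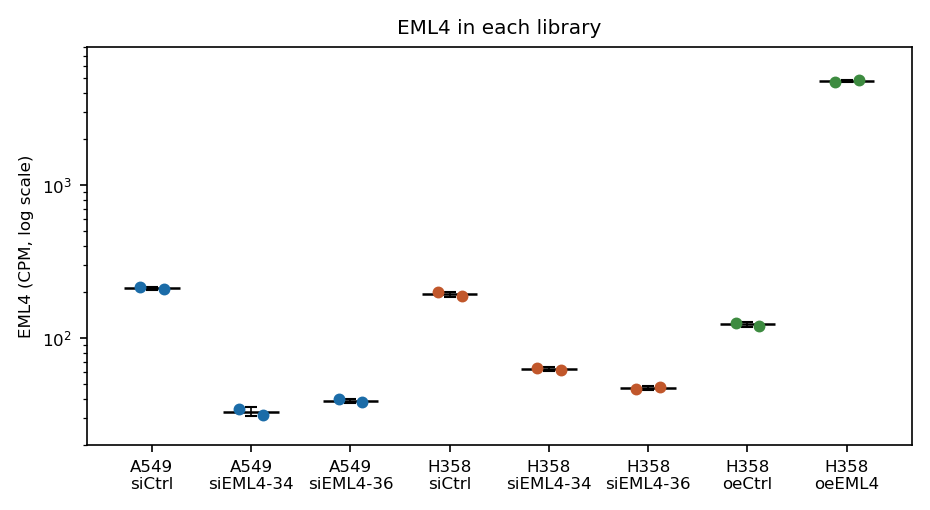
EML4 level in CPM (log axis) in each of the 8 groups, with a point per library and a bar at the mean. The EML4 siRNA groups lie between 33.1 and 62.9 CPM, their controls at 212 and 194 CPM, and the overexpression group at 4790 CPM against 123 CPM in its control.

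In A549, MET, the receptor of hepatocyte growth factor, rose from 207 ± 3.5 CPM with the control siRNA to 640 ± 43 and 595 ± 6.9 CPM with siRNAs 34 and 36 (1.57, SE 0.044, adjusted p = 4.9e-27 in edgeR). SLC2A3, a glucose transporter, rose from 30.6 ± 0.68 to 95.4 ± 11 and 61.7 ± 0.67 CPM (1.32, SE 0.076). H3F3A, which encodes histone H3.3, rose from 104 ± 4.7 to 251 ± 5.1 and 235 ± 2 CPM (1.23, SE 0.049), and RBPJ, the DNA-binding factor of Notch signalling, from 30.6 ± 0.87 to 74.1 ± 1.4 and 65.2 ± 1.8 CPM (1.18, SE 0.059). The methionine sulfoxide reductase gene MSRB3 (1.23), the amino acid transporter gene SLC36A1 (1.31), the chromatin protein gene BANF1 (1.18) and the HOXA-cluster RNA HOTAIRM1 (1.18) also rose. The pseudogene POM121L9P (1.58), whose reads may belong to its copies, and P4HA2-AS1 (1.25), with exons partly shared with a gene on the opposite strand, rose and are uncertain. The annotated 3′ UTRs of MET, H3F3A, RBPJ, MSRB3 and BANF1 hold the word GACGTA, and those of RBPJ, SLC2A3 and SLC36A1 hold GACAGTA. For genes with either word, loss of EML4 cannot be told apart from an action of the control siRNA, a candidate weighed below. Genes without the words were compared with the same control siRNA, so such an action is not excluded for them either.

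The genes that fell furthest in A549 included VAV3, a guanine nucleotide exchange factor, which went from 16.1 ± 1.3 CPM to 6.91 ± 0.59 and 8.72 ± 1.1 CPM (-1.06, SE 0.099), and TM4SF20, a membrane protein, from 33.4 ± 0.17 to 14.4 ± 1.6 and 18.6 ± 0.39 CPM (-1.03, SE 0.1). DPH5, an enzyme of diphthamide synthesis, fell from 32.4 ± 0.36 to 25.4 ± 0.2 and 11.4 ± 0.36 CPM (-0.93, SE 0.082), with a 3′ UTR that holds the word GTCGAAA. FERMT3, which activates integrins (-1.78), the ubiquitin ligase gene TRIM31 (-1.02) and the small GTPase gene RASL11A (-0.94) fell from levels near 5 CPM. ACRC (-1.82), NECAB2 (-1.42), CUZD1 (-1.11) and FBXW10 (-0.93) completed the 10 named genes. In all, 4236 genes changed, 2253 higher and 1983 lower, and 351 by at least 2-fold. The higher share was 53.2%, but 46.3% under RLE scaling, 45.8% with DESeq2, 46.3% with the experiment alone and 49.5% without genes holding GACGTA or GACAGTA in the 3′ UTR, so the larger direction depends on the method. The 2 siCtrl libraries of A549 lay further apart than those of any other group (chi-square per gene 10.5, next 5.18 in siEML4-34 of A549). Leaving out siCtrl replicate 1 lowered the count to 2261.

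Lists of cholesterol synthesis, matrix, unfolded protein response and hypoxia genes were higher in A549. Counts in square brackets in this and later paragraphs are those adjusted over the list alone, beside those over all genes tested. Of the SREBP2 targets of cholesterol synthesis, 16 [20] rose and 0 [0] fell of 23, among them MVD (0.52), which acts in the mevalonate pathway (camera adjusted p = 9.6e-11). Of matrix and matrix protease genes, 16 [19] rose and 1 [2] fell of 29, with the collagen VI chain COL6A2 at 0.68 (camera adjusted p = 1.1e-05). Of the genes of the unfolded protein response of the endoplasmic reticulum, 12 [14] rose and 3 [4] fell of 22; the disulfide isomerase gene PDIA4 (1.15) and SEL1L (0.71), part of the degradation machinery, rose, and PDIA6 fell with siRNA 36 and rose with siRNA 34 (-0.25 on average; camera adjusted p = 1.1e-04). Of hypoxia genes, 8 [8] rose and 1 [1] fell of 22, with the histone demethylase gene KDM3A (0.62) and NDRG1 (0.62) highest (camera adjusted p = 2.2e-04). These 4 lists also passed with an estimated correlation (adjusted p = 0.0055, 0.011, 0.019 and 0.019). PDIA4, SEL1L and KDM3A hold GACAGTA in the 3′ UTR, and PDIA6 holds GTCGAAA and has exons partly overlapped on the opposite strand.

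DNA replication genes were lower in A549 as a list: 2 [2] rose and 17 [17] fell of 35, the sliding clamp gene PCNA (-0.39) and MCM10 (-0.39) among them (camera adjusted p = 3.4e-07, and 0.074 with an estimated correlation). Of NRF2 targets, 2 [2] rose and 15 [16] fell of 23, led by the reductase gene AKR1B10 (-0.46; camera adjusted p = 1.1e-04, and 0.074 with an estimated correlation). Of MYC targets, 2 [3] rose and 15 [15] fell of 23, with POLR1B, a subunit of RNA polymerase I, at -0.34 and a 3′ UTR that holds GACAGTA (camera adjusted p = 3.5e-05, and 0.09 with an estimated correlation). Of nuclear-encoded respiratory-chain genes, 0 [0] rose and 12 [13] fell of 29, COX7B (-0.38) lowest (camera adjusted p = 1.9e-04, and 0.24 with an estimated correlation). Heat-shock genes (2 [2] rose and 10 [11] fell of 14; HSPH1 -0.31, with GACGTA in its 3′ UTR), mitotic genes (1 [2] rose and 14 [17] fell of 34; ANLN -0.27) and ribosomal protein genes (2 [2] rose and 15 [16] fell of 36) were lower as lists. Their camera adjusted p was 1.2e-04, 3.4e-04 and 4.5e-04 (adjusted p = 0.074, 0.24 and 0.46 with an estimated correlation), and ribosomal proteins lost the call in fry (adjusted p = 0.077).

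Of integrin and focal adhesion genes, 9 [11] rose and 2 [2] fell of 27, with ITGB4, the laminin-binding integrin chain, at 0.75 (camera adjusted p = 4.1e-04, and 0.088 with an estimated correlation). Of TFEB targets of lysosome and autophagy, 9 [9] rose and 1 [3] fell of 21, with the autophagy kinase gene ULK1 at 0.51 (camera adjusted p = 0.0033, and 0.16 with an estimated correlation). Fatty acid synthesis genes (8 [9] rose and 1 [2] fell of 14; ACSS2 0.38, the desaturase gene SCD 0.33) and TGF-beta targets (9 [9] rose and 2 [2] fell of 21; LTBP2 0.44, TGFBI 0.33) were higher. Their camera adjusted p was 8.9e-04 and 0.011 (adjusted p = 0.074 and 0.074 with an estimated correlation). TGF-beta targets lost the call once genes with GACGTA or GACAGTA in the 3′ UTR were left out, a choice made after the data were seen (camera adjusted p = 0.062). ATF4 targets (9 [9] rose and 3 [3] fell of 27; DDIT4 0.72) and glycolytic genes (8 [10] rose and 3 [3] fell of 17; ENO2 0.42) passed at 0.041 and 0.041, both higher (adjusted p = 0.28 and 0.47 with an estimated correlation). Without siCtrl replicate 1 their camera adjusted p became 0.06 and 0.1. The ATF4 call was also lost without siEML4-34 replicate 1 (0.062) and the glycolysis call without siEML4-36 replicate 2 (0.053). With lists tested in the experiment alone, a choice made after the data were seen, the calls of ATF4 targets (0.12), glycolysis (0.2) and TGF-beta targets (0.094) were lost.

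The other 18 lists did not pass camera in A549 (adjusted p from 0.11 to 0.98). Among those tied to shape and spread of cells, CLDN1, a claudin of tight junctions, rose from 140 ± 4.6 to 341 ± 16 and 285 ± 8.7 CPM (1.15, SE 0.048), with GACAGTA in its 3′ UTR. EML family (1 [2] rose and 3 [3] fell of 12), tubulins and microtubule regulators (8 [8] rose and 7 [11] fell of 30) and actin cytoskeleton (6 [6] rose and 1 [1] fell of 32) did not pass. Membrane protrusions (5 [5] rose and 5 [8] fell of 28) and mesenchymal genes (6 [6] rose and 2 [3] fell of 22) missed the threshold too. Epithelial junctions (4 [4] rose and 7 [8] fell of 29) and YAP and TEAD targets (3 [3] rose and 5 [7] fell of 24) were not called either. Interferon-stimulated genes (3 [3] rose and 2 [2] fell of 24), NF-kB and cytokine genes (6 [8] rose and 9 [10] fell of 27) and RAS-MAPK output (4 [4] rose and 8 [8] fell of 24) did not pass. Mitochondrially encoded mRNAs (0 [0] rose and 0 [0] fell of 13), histones (2 [0] rose and 0 [0] fell of 18) and m6A machinery (2 [2] rose and 4 [5] fell of 20) missed the threshold too. Lung lineage genes (1 [1] rose and 1 [1] fell of 13) and vesicle traffic genes (3 [3] rose and 6 [7] fell of 22) were not called either. Markers of fibroblasts (0 [0] rose and 1 [0] fell of 6), leukocytes (0 [0] rose and 0 [0] fell of 4) and endothelium (0 [0] rose and 1 [1] fell of 7) did not pass. Median, mean and test direction differed in sign for membrane protrusions (0.01, 0.01, down), epithelial junctions (0, 0.03, down), interferon-stimulated genes (-0.02, 0.1, down), RAS-MAPK output (0, 0.1, down) and endothelial markers (0.47, 0.29, down).

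Interferon-stimulated genes were higher in H358 as a list. MX1, an antiviral GTPase, rose from 10.2 ± 0.98 CPM to 46.3 ± 3 and 29.1 ± 0.99 CPM with siRNAs 34 and 36 (1.84, SE 0.099, adjusted p = 2.5e-17 in edgeR). IFI6 rose from 51.7 ± 4.1 to 175 ± 8.4 and 123 ± 3.5 CPM (1.51, SE 0.067), and IFI27 from 41.4 ± 1.4 to 124 ± 2.1 and 97.3 ± 1.3 CPM (1.41, SE 0.065). MX1, IFI6 and IFI27 moved further with siRNA 34, although it left more EML4 than siRNA 36 (62.9 and 47.3 CPM). Of the interferon-stimulated genes, 18 [20] rose and 1 [2] fell of 25, also IFI44L (1.31), MX2 (0.99) and XAF1 (1.6) (camera adjusted p = 1.0e-14, and 3.8e-04 with an estimated correlation). EPSTI1 (0.99) lost the call without siCtrl replicate 1 (adjusted p = 0.06). PPP2R1B, a scaffold of protein phosphatase 2A, rose from 53.7 ± 1.7 to 111 ± 3.4 and 111 ± 4.3 CPM (1.04, SE 0.055), as did the arrestin-like gene ARRDC4 (1.01), the transcription factor gene KLF2 (0.97) and RPSAP52 (1), a pseudogene whose reads are uncertain. EPSTI1 holds GACGTA and IFI44L GACAGTA in the 3′ UTR, and the exons of XAF1 are partly overlapped on the opposite strand. IFIT1, IFIT2 and IFIT3 had 0 counts in all 12 siRNA libraries.

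NF-kB and cytokine genes were lower in H358 as a list. IL32, a cytokine, went from 14.9 ± 0.3 CPM to 2.75 ± 0.77 and 7.61 ± 0.51 CPM (-1.72, SE 0.1, adjusted p = 9.2e-16 in edgeR), and the chemokine gene CXCL8 from 240 ± 3.7 to 105 ± 7.4 and 163 ± 4 CPM (-0.87, SE 0.045). CSF2, which encodes GM-CSF, fell from 13.7 ± 0.7 to 3.78 ± 0.05 and 7.97 ± 0.54 CPM (-1.31, SE 0.1), and BIRC3, an inhibitor of apoptosis induced by NF-kB, from 48.2 ± 2.8 to 20.8 ± 2.6 and 32.1 ± 2.8 CPM (-0.9, SE 0.06). Of the NF-kB and cytokine genes, 0 [0] rose and 18 [21] fell of 26, LCN2 at -2.09 (camera adjusted p = 1.0e-14, and 0.0051 with an estimated correlation). The other named genes that fell were the receptor genes TNFRSF9 (-1.46) and TREM1 (-1.07), the cytokine gene IL1A (-1.35), the adhesion molecule gene ICAM1 (-0.89), with exons partly overlapped on the opposite strand, the collagen gene COL17A1 (-0.87) and LAPTM5 (-0.86). In all, 2939 genes changed, 1158 higher and 1781 lower, and 117 by at least 2-fold. The count was 1747 without siCtrl replicate 1 and 1514 without siCtrl replicate 2.

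Cholesterol synthesis, unfolded protein response and matrix genes, higher in A549 as lists, were lower in H358. Of cholesterol synthesis genes, 0 [0] rose and 18 [21] fell of 23 (MVD (-0.47) and MSMO1 (-0.41); camera adjusted p = 1.2e-16). Of fatty acid synthesis genes, 0 [0] rose and 7 [7] fell of 14 (ACSS2 (-0.61) and FASN (-0.34); 1.1e-06). Of the unfolded protein response genes, 1 [1] rose and 17 [18] fell of 22 (the chaperone genes HYOU1 (-0.64) and DNAJB11 (-0.53); 7.2e-15). Of ATF4 targets, 1 [1] rose and 18 [19] fell of 27 (the cystine transporter gene SLC7A11 (-0.58), ATF3 (-0.54); 3.2e-12). Of lysosome and autophagy genes, 1 [1] rose and 13 [13] fell of 21 (CTSL (-0.61) and MAP1LC3B (-0.47); 1.7e-08). Of matrix genes, 1 [1] rose and 17 [18] fell of 29 (camera adjusted p = 1.3e-12). Of mesenchymal genes, 1 [1] rose and 9 [9] fell of 22 (FN1 (-0.68), fibronectin; 1.1e-04). Epithelial junctions (1 [1] rose and 14 [18] fell of 30; SPINT1 (-0.37); 5.8e-06) and actin cytoskeleton genes (0 [0] rose and 12 [12] fell of 32; FLNA (-0.35), a filamin; 8.0e-04) were lower. Of NRF2 targets, 0 [0] rose and 13 [16] fell of 23 (HMOX1 (-0.32); 7.5e-06). Of DNA replication genes, 10 [12] rose and 0 [0] fell of 35, with GINS3 at 0.63, GACGTA in its 3′ UTR and exons partly overlapped (camera adjusted p = 6.9e-08). In the order given, adjusted p with an estimated correlation was 3.8e-04, 0.016, 3.8e-04, 0.0066, 0.017, 3.8e-04, 0.03, 0.023, 0.049, 0.04 and 0.049. DNAJB11 has exons partly overlapped on the opposite strand.

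The share of counts from the mitochondrial genome moved with these lists, from 6.66 ± 0.34% in the H358 control to 8.38 ± 0.18% with siRNA 34 and 7.79 ± 0.0031% with siRNA 36. Of the mitochondrially encoded mRNAs, 6 [9] rose and 0 [0] fell of 13 (camera adjusted p = 4.0e-05, and 0.16 with an estimated correlation). MT-CYB (0.41) and MT-ND2 (0.34) lost the call without siCtrl replicate 2 (adjusted p = 0.08 and 0.061). Lower lists whose call was lost with an estimated correlation were ribosomal proteins (0 [0] rose and 22 [27] fell of 36; RPS2 (-0.33) and RPLP1 (-0.31), the latter with GACGTA), vesicle traffic (1 [1] rose and 14 [17] fell of 22; the cargo receptor gene LMAN1 (-0.43)), respiratory chain (0 [0] rose and 11 [13] fell of 29), the EML family (1 [1] rose and 3 [4] fell of 12, EML4 itself among them) and membrane protrusions (2 [2] rose and 6 [7] fell of 27; MSN (-0.31)). Their camera adjusted p was 2.9e-11, 1.8e-09, 7.7e-06, 0.014 and 0.012, and adjusted p = 0.13, 0.058, 0.13, 0.058 and 0.062 with an estimated correlation. Of m6A machinery genes, 8 [9] rose and 2 [3] fell of 20, with the reader gene YTHDF3 at 0.33 and GACGTA in its 3′ UTR, and of MYC targets 6 [6] rose and 0 [0] fell of 23 (camera adjusted p = 0.016 and 0.0039; adjusted p = 0.16 and 0.16 with an estimated correlation). Without siCtrl replicate 1 these 2 became 0.073 and 0.064.

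Tubulins and microtubule regulators were lower in H358 as a list (2 [2] rose and 8 [9] fell of 30; MAP1B (-0.35)), although STMN1, which destabilises microtubules, rose (0.53). Heat-shock genes (2 [2] rose and 5 [6] fell of 14), integrins and focal adhesion genes (2 [4] rose and 11 [14] fell of 27; ITGAV (-0.65)) and glycolytic genes (0 [1] rose and 6 [8] fell of 17) were also lower. Camera adjusted p for the 4 lists was 0.047, 0.047, 0.014 and 0.0039, and adjusted p = 0.14, 0.22, 0.16 and 0.24 with an estimated correlation. The tubulin call was lost without siCtrl replicate 2 (0.11), siEML4-34 replicate 1 (0.09) or 2 (0.064), siEML4-36 replicate 1 (0.081) or 2 (0.066), and without genes holding GACGTA or GACAGTA (0.057). The heat-shock call was lost without siCtrl replicate 2 (0.25), siEML4-34 replicate 1 (0.16), siEML4-36 replicate 1 (0.071) or 2 (0.081), the glycolysis call without siCtrl replicate 2 (0.088), and the integrin call without siEML4-36 replicate 1 (0.053). In the experiment alone the calls of tubulins (0.26), heat shock (0.16) and glycolysis (0.054) were lost. The other 10 lists did not pass (camera adjusted p from 0.12 to 0.9). Mitosis (1 [1] rose and 3 [2] fell of 34), YAP and TEAD targets (3 [6] rose and 6 [7] fell of 23) and TGF-beta targets (3 [4] rose and 6 [6] fell of 21) did not pass. RAS-MAPK output (4 [4] rose and 5 [7] fell of 24), hypoxia genes (5 [6] rose and 2 [4] fell of 22) and histones (1 [1] rose and 1 [1] fell of 16) missed the threshold too. Lung lineage genes (0 [1] rose and 2 [3] fell of 15) and fibroblast markers (0 [0] rose and 1 [1] fell of 6) were not called either. Leukocyte markers (0 [0] rose and 0 [0] fell of 5) and endothelial markers (0 [0] rose and 1 [1] fell of 7) were among them. Median, mean and test direction differed in sign for YAP targets (-0.03, 0.01, down), hypoxia genes (0.09, -0.01, up), RAS-MAPK output (0.01, 0.02, down) and leukocyte markers (0.01, -0.33, up).

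**Figure D2:**
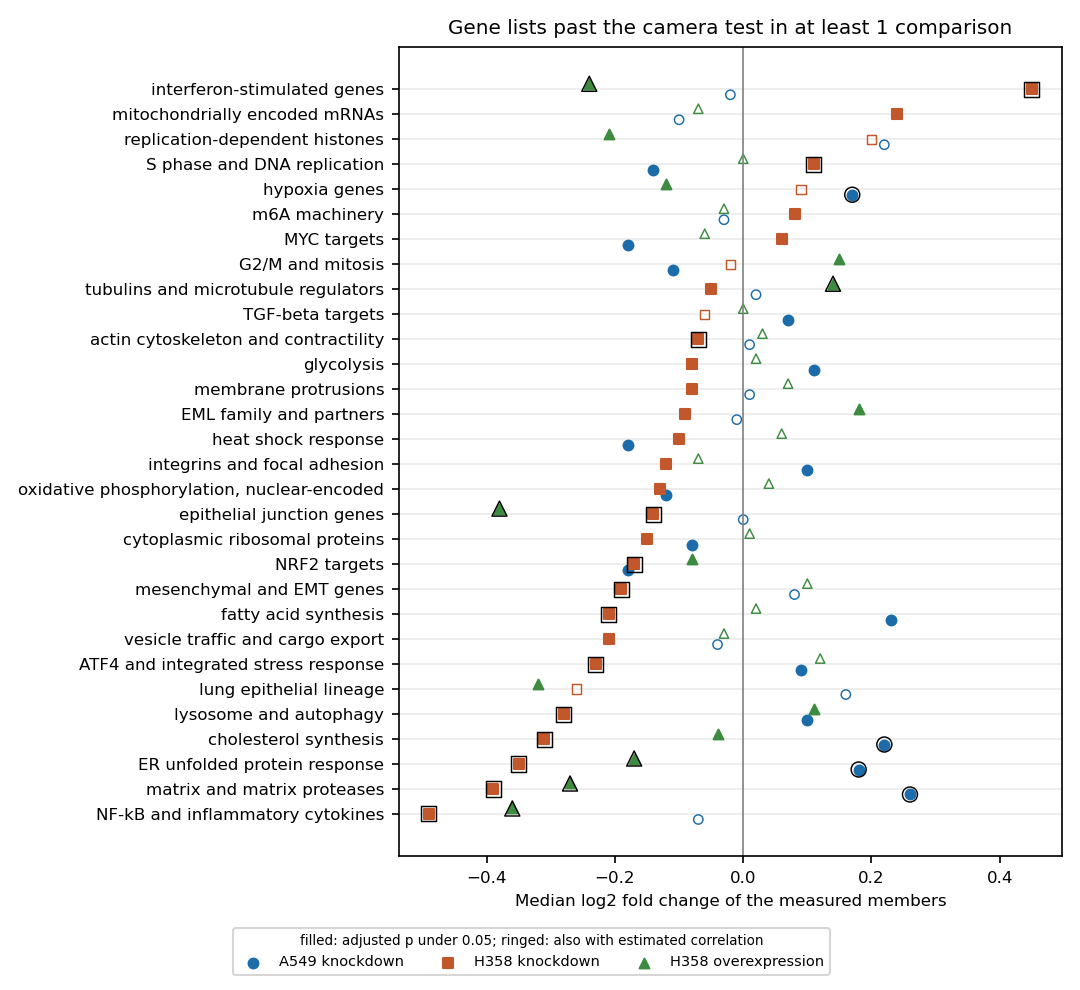
Median log2 fold change of the measured members of each gene list reported here (horizontal axis) that passed camera in at least 1 of the 3 main comparisons, with circles for A549 knockdown, squares for H358 knockdown and triangles for H358 overexpression; filled points passed at an adjusted p under 0.05 and ringed points passed with an estimated correlation too. Cholesterol synthesis (0.22 and -0.31) and the unfolded protein response (0.18 and -0.35) had medians of opposite sign in A549 and H358.

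Of the genes changed alike in both lines, JAG1, a Notch ligand, rose in A549 (0.66, SE 0.042) and H358 (0.73, SE 0.041), as did RBPJ (1.18 and 0.77) and MET (1.57 and 0.83). WWTR1, the transcriptional partner of TEAD factors, rose too (0.64 and 0.64). PPP2R1B (0.8 and 1.04), the survival gene MCL1 (0.75 and 0.47), BANF1 (1.18 and 0.65), H3F3A (1.23 and 0.54), the GTPase gene RHOB (0.59 and 0.55) and STMN1 (0.52 and 0.53) completed the 10 with the strongest tests. Of these 10, JAG1, RBPJ, MET, WWTR1, BANF1, H3F3A and RHOB hold GACGTA or GACAGTA in the 3′ UTR and PPP2R1B, MCL1 and STMN1 hold neither. Holding neither word does not exclude an action of the control siRNA on a gene. Among genes higher in both lines with a searched 3′ UTR, 141 of 260 (54.2%) held either word, against 422 of 3762 (11.2%) called in neither line and 16 of 276 (5.8%) lower in both. The words were themselves picked from these fold changes.

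Across genes, 670 changed the same way in both lines, 342 higher and 328 lower. Independent lists of these sizes, with each of the 20135 tested genes equally likely to be called, would share 130 and 175. Another 469 changed in opposite directions, 349 of them higher in A549 and lower in H358 (199 for independent lists) and 120 the reverse (114). The log2 fold changes had r = 0.076 over 10483 genes, which are not independent replicates. FN1, chosen after its values were seen, rose in A549 (0.31) and fell in H358 (-0.68). The higher share of the 670 was 51%, but 39.6% under RLE scaling, 38.7% with DESeq2, 48.1% with limma-voom, 46.9% with each experiment alone, 37.2% without genes holding GACGTA or GACAGTA and 48.5% without A549 siCtrl replicate 2. Without H358 siCtrl replicate 1 or 2 the count was 425 or, to 2 digits, 3.6e+02, and without genes holding either word it was 495. A model with a knockdown effect common to the lines, fitted to the 12 siRNA libraries, called 1282 of 18011 genes, 751 higher and 531 lower (58.6% higher, against 48.1% under RLE scaling, 46.3% with DESeq2, 48.7% with no low-count filter, 49.9% without H358 siEML4-34 replicate 2 and 50% and 46.5% without H358 siEML4-36 replicate 1 and 2), 1957 with DESeq2 and 815 without A549 siCtrl replicate 2.

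**Figure D3:**
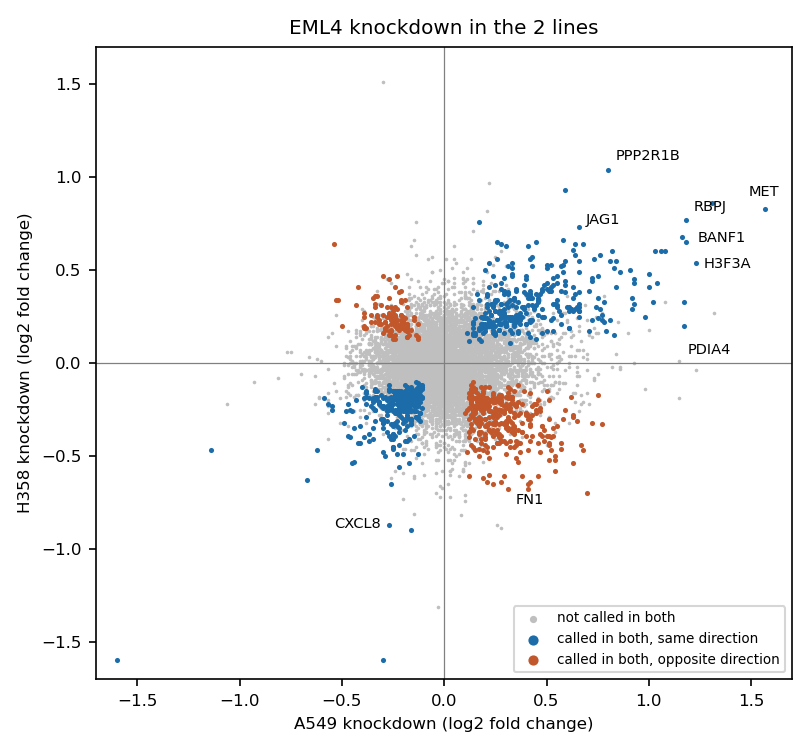
Log2 fold change on EML4 knockdown in A549 (horizontal) and H358 (vertical) for 9364 genes at 5 CPM or more in both lines, with 600 genes called in both lines in the same direction (blue) and 432 in opposite directions (orange). Axes stop at 1.6, where EML4 and IL32 are drawn, and MET (1.57 and 0.83) and PPP2R1B (0.8 and 1.04) stand at the upper right.

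The knockdown effect itself differed between the lines for 3120 genes, 1900 with a larger value in A549 and 1220 with a larger value in H358. The difference passed camera for 21 lists, 14 toward A549 and 7 toward H358, and 11 of the 21 also with an estimated correlation. Cholesterol synthesis (20 [22] rose and 0 [0] fell of 23), the unfolded protein response (20 [21] rose and 0 [0] fell of 22), matrix genes (18 [20] rose and 0 [0] fell of 29) and NF-kB and cytokine genes (19 [19] rose and 0 [2] fell of 27) were relatively higher in A549, where rose and fell stand for the difference (camera adjusted p = 1.7e-22, 1.6e-20, 1.2e-14 and 2.5e-11, and 2.0e-04, 2.0e-04, 2.1e-04 and 0.0093 with an estimated correlation). DNA replication (0 [0] rose and 19 [28] fell of 35) and interferon-stimulated genes (2 [2] rose and 10 [11] fell of 25) were relatively higher in H358 (camera adjusted p = 9.3e-16 and 9.6e-05, and 0.01 and 0.0093 with an estimated correlation). The most extreme fitted differences belonged to genes near 0 CPM in 1 line, PRCAT47 and GAL3ST1 for example, whose fold depends on the prior count and sets no bound.

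The siRNAs against EML4 shared many of their changes. In A549, siRNA 34 changed 3304 genes and siRNA 36 changed 3783, with 1128 higher and 825 lower under both, where independent lists would share 188 and 125, and 28 opposite. The higher share of those shared was 57.8%, but 49% under RLE scaling and 48.1% with DESeq2. In H358 they changed 2961 and 1675 genes, with 490 higher and 820 lower under both (37.1 and 92.2 for independent lists) and 2 opposite. In 20 simulations of unchanged groups, with each library drawn independently, there were 0 shared calls. These simulations held no shift common to the 2 libraries of a group, so they cannot exclude one. They also gave all groups the same dispersion per gene, although the A549 control libraries varied more than the others. Both siRNAs are compared with the same 2 control libraries. The covariance of their fold changes was 0.085 in A549 and 0.067 in H358, against 0.015 and 0.014 simulated, differences of 0.069 and 0.053 (r = 0.64 and 0.676, against 0.497 and 0.517 simulated). The 2 controls cannot be split, so part of the excess may come from the shared controls. The shared total of 1953 in A549 became 1117 without siCtrl replicate 1, 1194 without siEML4-34 replicate 2 and 1286 without siEML4-36 replicate 1, and that of 1310 in H358 became 827 and 671 without siCtrl replicate 1 and 2 and 799 and 622 without siEML4-36 replicate 1 and 2. For siRNA 34 alone the A549 count became 2056 without siCtrl replicate 1 and 1852 without siEML4-34 replicate 2, and the H358 count 1896 and 1727 without siCtrl replicate 1 and 2 and 1897 without siEML4-34 replicate 1. For siRNA 36 alone the A549 count became 2240 without siCtrl replicate 1 and 2127 and 2271 without siEML4-36 replicate 1 and 2, and the H358 count 1028, 810, 1054 and 684 without siCtrl or siEML4-36 replicates 1 and 2 in that order.

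They also differed from each other. In A549, the airway mucin genes MUC5AC (-1.09) and MUC5B (-0.91) were lower and the immediate-early gene EGR1 (1.29), PDIA6 (1.01) and DPH5 (1.16) higher with siRNA 34 than with siRNA 36. PDIA6 lay at 556 ± 12 and 276 ± 1.5 CPM with siRNAs 34 and 36, and at 466 ± 25 CPM in the control. PDIA6 and DPH5 hold the word GTCGAAA in the 3′ UTR. In H358, IL32 (-1.49), the cytokine genes TNFSF15 (-1.16; GACAGTA in its 3′ UTR) and CSF2 (-1.08) were lower and MX1 (0.67) higher with siRNA 34. More EML4 was left in H358 by siRNA 34 than by siRNA 36 (62.9 and 47.3 CPM). The larger changes of IL32, CSF2 and MX1 with siRNA 34 thus did not follow the depth of knockdown. The pseudogene HNRNPA1P48 was lower with siRNA 34 in A549 (-1.7) and is uncertain. The difference reached 1111 genes in A549 (717 with the experiment alone) and 262 in H358. Leaving out siEML4-34 replicate 1 or 2 gave 647 or 664 in A549 and 137 or 157 in H358, and leaving out siEML4-36 replicate 1 or 2 gave 413 or 444 in A549 and, without replicate 2, 94 in H358.

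Overexpression of EML4 in H358 raised MMP14, a membrane-bound matrix metalloproteinase, from 89.6 ± 5.2 to 172 ± 4.3 CPM (0.94, SE 0.081, adjusted p = 3.4e-11 in edgeR) and the homeobox gene HOXB2 from 45 ± 3.8 to 86 ± 2.8 CPM (0.93, SE 0.096). WT1, a transcription factor (1.15), CORO2B, a coronin (1.12), the growth factor gene BMP6 (0.96), SLC22A23 (1.01) and the pseudogene MYH16 (1.02) rose, the last 2 uncertain from overlapped exons or copies. Among the genes that fell were EDN1, which encodes endothelin-1, from 28 ± 0.85 to 14 ± 0.94 CPM (-1, SE 0.091), COL8A1 from 176 ± 1.1 to 96.6 ± 0.49 CPM (-0.87, SE 0.077) and INHBA, an activin subunit, from 23.5 ± 3.1 to 10.9 ± 1 CPM (-1.1, SE 0.14). The receptor gene TLR4 (-1.09), ST6GALNAC5 (-0.94), the cytokine genes CSF3 (-0.92) and CX3CL1 (-0.87) and the pseudogene GTF2IP7 (-0.88), which is uncertain, fell as well. In all, 3137 genes changed, 1696 higher and 1441 lower, and 83 by at least 2-fold. The higher share was 54.1%, but 46.2% under RLE and 48.6% under upper-quartile scaling, 45.9% with DESeq2, 49.8% with the experiment alone and 48.9% without oeEML4 replicate 2. The count was 4993 with the experiment alone. Without oeCtrl replicate 1 or 2 it was 1726 or 1745, and without oeEML4 replicate 1 or 2 it was 1933 or 1859.

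HIST1H3G (1.06) and TRHDE-AS1 (0.94), 2 of the 10 genes that rose furthest, lost the call when any 1 library was left out, with adjusted p of 0.18, 0.11, 0.087 and 0.17 for HIST1H3G and 0.21, 0.056, 0.13 and 0.12 for TRHDE-AS1 without oeCtrl replicates 1 and 2 and oeEML4 replicates 1 and 2 in that order. C8orf88 (0.96), with overlapped exons, lost it without oeCtrl replicate 1 (0.078) or oeEML4 replicate 1 (0.069). Of those that fell, HIST1H2BA (-0.98) lost it without oeCtrl replicate 1 (0.074) or oeEML4 replicate 2 (0.11), and ALDH1L1 (-0.87) without oeEML4 replicate 1 (0.063). The overexpression control differed from the H358 siRNA control in level: VIM, the mesenchymal filament gene, lay at 1660 ± 20 and 46.6 ± 2.7 CPM, and TNN at 2.36 ± 0.18 and 682 ± 11 CPM. These 2 genes were chosen after their values were seen.

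Epithelial junction genes were lower on overexpression as a list: 0 [0] rose and 22 [23] fell of 30, among them MARVELD2 (-0.78), a tight-junction protein gene, and EPCAM (-0.57; camera adjusted p = 3.5e-17). Of matrix genes, 1 [2] rose and 13 [13] fell of 30, with the laminin chain LAMA3 (-0.65) among the lowest while MMP14 rose (camera adjusted p = 7.7e-07). Of NF-kB and cytokine genes, 2 [2] rose and 14 [16] fell of 28 (the chemokine gene CCL20 (-0.84); camera adjusted p = 1.1e-07). Of interferon-stimulated genes, 0 [0] rose and 12 [15] fell of 30 (camera adjusted p = 7.7e-07). Of unfolded protein response genes, 0 [0] rose and 10 [11] fell of 22 (SEC24D (-0.33); camera adjusted p = 1.9e-06). Of the interferon-stimulated genes that fell, RSAD2 (-0.58) lost its call without oeEML4 replicate 1 (adjusted p = 0.082). Tubulins and microtubule regulators were higher as a list: 12 [15] rose and 2 [2] fell of 31, among them TUBB6 (0.72) and TUBA1A (0.68), both with exons partly overlapped on the opposite strand (camera adjusted p = 2.4e-04). These 6 lists also passed with an estimated correlation (adjusted p = 0.0042, 0.0042, 0.029, 0.0042, 0.0082 and 0.029). TUBB6 holds GACGTA and INHBA and COL8A1 hold GACAGTA in the 3′ UTR; in this comparison the z of GACGTA was 1.08, inside the permuted range (largest absolute value 5.19).

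Another 8 lists passed on overexpression and lost the call with an estimated correlation. Mitosis (13 [19] rose and 1 [1] fell of 34; the spindle gene TPX2 (0.32)), lysosome and autophagy (8 [10] rose and 0 [2] fell of 23; RRAGD (0.56)) and the EML family (5 [6] rose and 1 [1] fell of 12, EML4 itself and EML1 0.71 among them) were higher. NRF2 targets (2 [4] rose and 7 [7] fell of 25; AKR1C2 (-0.79)), hypoxia genes (1 [2] rose and 7 [7] fell of 22; the glucose transporter gene SLC2A1 (-0.41)) and histones (0 [0] rose and 4 [5] fell of 18; HIST2H2BE (-0.42)) were lower, as were lung lineage genes (1 [1] rose and 4 [4] fell of 15; HOPX (-0.65) and ABCA3 (0.57)) and cholesterol synthesis (1 [1] rose and 5 [5] fell of 23; MSMO1 (-0.39)). In the order given, camera adjusted p was 1.2e-05, 0.0047, 0.0065, 0.0065, 0.0093, 0.036, 0.038 and 0.035, and adjusted p = 0.18, 0.15, 0.051, 0.18, 0.051, 0.15, 0.12 and 0.15 with an estimated correlation. For cholesterol synthesis the median was -0.04, the mean 0.01 and the test down. HOPX lost its own call without oeEML4 replicate 1 (adjusted p = 0.05). Lung lineage genes lost the call without oeCtrl replicate 1 (0.068) or oeEML4 replicate 1 (0.12), histones without oeCtrl replicate 2 (0.081) or oeEML4 replicate 2 (0.12), and cholesterol synthesis without oeEML4 replicate 1 (0.14). In the experiment alone histones (0.07) and lung lineage genes (0.089) lost the call.

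The other 23 lists did not pass on overexpression (camera adjusted p from 0.051 to 1). Actin cytoskeleton (10 [11] rose and 4 [6] fell of 33), membrane protrusions (8 [10] rose and 4 [4] fell of 28) and mesenchymal genes (8 [9] rose and 8 [9] fell of 24) did not pass. Integrins (7 [10] rose and 9 [10] fell of 27), DNA replication (3 [3] rose and 5 [6] fell of 35) and ATF4 targets (8 [10] rose and 4 [5] fell of 27) missed the threshold too. Heat shock (4 [5] rose and 1 [1] fell of 15) and fatty acid synthesis (3 [4] rose and 2 [3] fell of 15) were not called either. YAP targets (7 [10] rose and 3 [3] fell of 24) and TGF-beta targets (7 [8] rose and 6 [7] fell of 22) were among them. RAS-MAPK output (5 [6] rose and 8 [9] fell of 24), MYC targets (2 [2] rose and 6 [7] fell of 24) and glycolysis (3 [4] rose and 5 [5] fell of 17) did not pass. Respiratory chain (3 [3] rose and 1 [1] fell of 30), mitochondrial mRNAs (0 [0] rose and 0 [0] fell of 13) and ribosomal proteins (7 [7] rose and 3 [3] fell of 39) missed the threshold too. M6A machinery (3 [4] rose and 4 [5] fell of 21), vesicle traffic (2 [2] rose and 2 [3] fell of 22) and fibroblast markers (0 [0] rose and 0 [0] fell of 7) were not called either. Leukocyte markers (0 [0] rose and 0 [0] fell of 5) and endothelial markers (0 [0] rose and 0 [0] fell of 7) were among them. Median, mean and test direction differed in sign for mesenchymal genes (0.1, 0.06, down) and glycolysis (0.02, 0.01, down), and a median or mean of 0 was met in DNA replication (0, -0.01, down), TGF-beta targets (0, 0.11, up) and m6A machinery (-0.03, 0, down).

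Genes that moved in opposite directions on knockdown and overexpression in H358 included JAG1 (0.73 and -0.6) and THBS1 (0.47 and -0.65), which encodes thrombospondin-1. MSN, which links actin to the membrane (-0.31 and 0.3), MRC2, a collagen receptor with partly overlapped exons (-0.43 and 0.55), TBC1D1 (-0.44 and 0.5), DHRS2 (0.37 and -0.63), the insulin receptor substrate gene IRS1 (0.35 and -0.38), INHBB (0.32 and -0.41) and FAM129A (-0.68 and 0.62) did so too. JAG1 and IRS1 hold GACGTA and FAM129A holds GACAGTA in the 3′ UTR. In all, 403 genes were reversed, 139 higher on knockdown and 264 lower (34.5% higher, but 50.5% with each experiment alone), where independent lists would share 82.9 and 150, and 489 moved the same way, 101 higher and 388 lower (97.5 and 127 for independent lists). The fold changes had r = 0.0004 over 10483 genes, which are not independent replicates. Lists called by camera at the preset correlation went both ways too. Epithelial junction, matrix, NF-kB and cytokine, unfolded protein response, NRF2 and cholesterol synthesis lists were lower both on knockdown and on overexpression in H358. Interferon-stimulated genes were higher on knockdown and lower on overexpression, and tubulin, lysosome and autophagy and EML family lists the reverse. The count of 403 was 608 with each experiment alone, 251 and 222 without siCtrl replicate 1 and 2, 230 and 242 without oeCtrl replicate 1 and 2, and 239 without oeEML4 replicate 2.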

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

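The test of GACGTA on the opposite strand, its test in the 5′ UTR and coding part, and the splits of the libraries were set before their results were seen; all other tests in this part were chosen after. Genes higher on knockdown in both lines often hold GACGTA or GACAGTA in the 3′ UTR: 54.2%, against 11.2% of genes called in neither line. Both words were picked for their high z along these same fold changes, so the choice can enlarge this excess, which is no separate test. The z of GACGTA in the 3′ UTR was 20.58 in A549 and 13.17 in H358 after adjustment for UTR length and GC content, beyond the permuted ranges (5.25 and 5.82), which argues against those features. Each range is the largest absolute z over all words in 200 permutations. Picking the strongest word thus did not reach the observed z in permuted fold changes. The reverse complement TACGTC had z = 0.12, against a factor that reads DNA on either strand, and GACGTA in the 5′ UTR and coding part had z = 7.6, beyond the permuted 5.25 but under the bound set for a word that acts anywhere in the mRNA. A candidate explanation is a seed-like action of the control siRNA, which represses genes with the word in the controls so that they appear higher with the EML4 siRNAs; siRNA sequences are not given in the sources used here. Loss of EML4 stays open and cannot be told apart from it. Of the genes higher in both lines, 12 with either word fell on overexpression and 13 rose (48.0% fell). Of those without either word, 24 fell and 13 rose (64.9% fell). Among all genes called on overexpression, 1441 fell and 1696 rose. The difference between 48.0% and 64.9% rests on few genes and was not tested, so it decides nothing.

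Of 11585 symbols at 5 CPM or more in the overexpression libraries, 430 were listed at 0 in all 12 siRNA libraries, TUBA1B (2080 ± 35 CPM in the overexpression control), RPS4X, TIMP1 and ITGA5 among them. Of those at 0 in the H358 siRNA libraries, 90.7% were also at 0 in A549, against 0.86% of the other symbols, and 43 exceed 100 CPM in the overexpression control. That argues against absent expression, and a candidate explanation is counting or annotation that differed between the experiments. Exons shared with a gene on the opposite strand (64.0% of these symbols, 40.5% of others, in GENCODE 29) covered at least 90% of the exonic bases in 1.6% of these symbols, which goes against them as the whole cause in that release; they stay open, because the annotation release of the counts is not given. Of the 858 list members tested, 30 are affected, and their knockdown effect was not measured, although they stayed in the list tests.

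The 2 controls labelled H358 differ: log levels had r = 0.87 over 6918 genes, where replicate pairs had at least 0.997 and the A549 and H358 siRNA controls 0.73, and 261 genes were at least 8-fold apart. The A549 control and the overexpression control had r = 0.77. Of 4841 genes at 5 CPM or more in the A549 control and the overexpression control, 65 lay under 0.5 CPM in the H358 siRNA control, which argues against counting or annotation as the whole cause. Of 4762 genes at 5 CPM or more in both siRNA controls, 2 lay under 0.5 CPM in the overexpression control. A batch of cultures or libraries (r = 0.87) and cells of another line or stock under the same label cannot be told apart, since each experiment is 1 batch. ANTXR1 was at 0 and 36.2 ± 1.1 CPM. Comparisons of knockdown with overexpression carry this difference, and no biological explanation was tested.

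Knockdown in both lines called 1282 genes, and 1 of 100 splits of the libraries within lines, the real one, gave as many. The highest other split gave 191. The splits dealt out single libraries and could part the 2 libraries of a group, which can lower their calls. The real grouping thus stood out from the spread between single libraries, but the splits cannot exclude chance between groups. The libraries of a group may come from 1 culture, so chance between cultures was not tested.

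A test of the difference between the lines in edgeR (adjusted p under 0.05, Benjamini-Hochberg) singled out 3120 of 20135 genes. Members that differed numbered 9 of 32 in actin cytoskeleton and contractility, 10 of 22 in mesenchymal and EMT genes, 15 of 27 in integrins and focal adhesion, 18 of 29 in matrix and matrix proteases, 19 of 35 in S phase and DNA replication, 8 of 34 in G2/M and mitosis, 12 of 25 in interferon-stimulated genes, 19 of 27 in NF-kB and inflammatory cytokines, 15 of 27 in ATF4 and integrated stress response, 20 of 22 in ER unfolded protein response, 4 of 14 in heat shock response, 20 of 23 in cholesterol synthesis, 10 of 14 in fatty acid synthesis, 9 of 21 in TGF-beta targets, 13 of 23 in MYC targets, 9 of 17 in glycolysis, 6 of 13 in mitochondrially encoded mRNAs, 10 of 36 in cytoplasmic ribosomal proteins, 5 of 20 in m6A machinery, 13 of 21 in lysosome and autophagy and 13 of 22 in vesicle traffic and cargo export. Of these lists, the call was lost with an estimated correlation for actin cytoskeleton and contractility (adjusted p = 0.073), integrins and focal adhesion (adjusted p = 0.069), G2/M and mitosis (adjusted p = 0.47), heat shock response (adjusted p = 0.23), TGF-beta targets (adjusted p = 0.11), glycolysis (adjusted p = 0.23), mitochondrially encoded mRNAs (adjusted p = 0.21), cytoplasmic ribosomal proteins (adjusted p = 0.66), m6A machinery (adjusted p = 0.23) and vesicle traffic and cargo export (adjusted p = 0.27).

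The log2 knockdown effect in A549 minus that in H358 follows each named gene that this test called. LCN2 1.45, IL32 1.42, CLDN1 1.34, CSF2 1.28, MSRB3 1.27, P4HA2-AS1 1.21, TREM1 1.21, IL1A 1.17 and ICAM1 1.16 had a larger value in A549. COL6A2 1.15, PDIA4 1.13, COL17A1 1.13, FAM129A 1.09, HYOU1 1.07, SLC2A3 1.05, DDIT4 1.04, MRC2 1 and ACSS2 0.99 had a larger value in A549. FN1 0.99, MVD 0.98, ITGB4 0.92, ITGAV 0.88, ULK1 0.81, TNFRSF9 0.81, BIRC3 0.75, MET 0.74 and CTSL 0.73 had a larger value in A549. DNAJB11 0.71, H3F3A 0.68, TGFBI 0.68, SLC7A11 0.67, LTBP2 0.66, FLNA 0.66, FASN 0.65, CXCL8 0.6 and LAPTM5 0.6 had a larger value in A549. MAP1LC3B 0.58, SEL1L 0.54, BANF1 0.53, NDRG1 0.53, MSMO1 0.52, SCD 0.51, ENO2 0.47, SLC36A1 0.45 and ATF3 0.42 had a larger value in A549. RBPJ 0.41, LMAN1 0.39, MAP1B 0.37, MSN 0.36, RPS2 0.34, KDM3A 0.33, SPINT1 0.32, MCL1 0.28 and TBC1D1 0.22 had a larger value in A549. PDIA6 0.2 and RPLP1 0.19 had a larger value in A549. EPSTI1 -3.36, NECAB2 -1.96, IFI6 -1.81, MX1 -1.81, ACRC -1.78, FERMT3 -1.51, TRIM31 -1.37, RASL11A -1.33 and IFI27 -1 had a larger value in H358. VAV3 -0.84, ARRDC4 -0.84, DPH5 -0.83, THBS1 -0.76, KLF2 -0.75, EML4 -0.74, MCM10 -0.66, PCNA -0.58 and MT-CYB -0.53 had a larger value in H358. COX7B -0.43, MT-ND2 -0.42, POLR1B -0.38, INHBB -0.31, ANLN -0.27, PPP2R1B -0.24 and IRS1 -0.23 had a larger value in H358. The EPSTI1 value rests on a level near 0 CPM in A549 and lost its call without A549 siCtrl replicate 1 (adjusted p = 0.16).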

How the results depend on the processing

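The processing alternatives were fixed before the data were examined, except 2 chosen after: leaving out genes with GACGTA or GACAGTA in the 3′ UTR, and lists in each experiment alone. Tests and genes chosen later are named as such where they are given. No called list and no named gene reversed its direction under any alternative run, but the larger of the higher and lower shares turned for several counts of genes, as given in the report where both shares are stated, and for the 2-fold limit and the block below. Under RLE and upper-quartile scaling, limma-voom, no low-count filter and the stricter filter, each count of genes lay within 1.5 times its reported value, and under DESeq2 all did but 1.

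A limit of 2-fold beside the adjusted p left 351 genes for A549 knockdown, 316 genes for siRNA 34 in A549, 343 genes for siRNA 36 in A549, 117 genes for H358 knockdown, 154 genes for siRNA 34 in H358, 53 genes for siRNA 36 in H358, 83 genes for overexpression, 64 genes for the siRNA difference in A549, 20 genes for the siRNA difference in H358, 315 genes for the difference between the lines, 107 genes for both siRNAs in A549, 21 genes for both siRNAs in H358, 6 genes for the same way in both lines, 2 genes for reversed by overexpression and 61 genes for knockdown in both lines, because it removes smaller changes by construction; the higher share was 16.7% of the 6 and 50% of the 2 reversed, 66.7% of the 21 for both siRNAs in H358. With each experiment fitted alone, overexpression called 4993 genes, the siRNA difference in A549 717 and reversal by overexpression 608. DESeq2 called 1957 genes for knockdown in both lines. The cause was not tested for these 4.

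Lists called fell to 5, 14 and 6 of 19, 27 and 14 in A549, H358 and overexpression with an estimated correlation, and the rotation test fry called 23 on overexpression. The cause was not tested for either. Without genes holding either word the counts were 3701 genes in A549, 2579 in H358, 495 the same way in both lines and 3.6e+02 reversed by overexpression, with 18 and 26 lists in A549 and H358. In each experiment alone 17, 24 and 15 lists were called, with 4, 3 and 2 lost and 2, 0 and 3 gained.

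Leaving out each library in turn gave ranges of 2261 to 4272 for A549 knockdown, 1852 to 3674 for siRNA 34 in A549, 2127 to 4091 for siRNA 36 in A549, 1514 to 2684 for H358 knockdown, 1727 to 2153 for siRNA 34 in H358, 684 to 1054 for siRNA 36 in H358, 1726 to 1933 for overexpression, 413 to 664 for the siRNA difference in A549, 94 to 184 for the siRNA difference in H358, 2254 to 3643 for the difference between the lines, 1117 to 2430 for both siRNAs in A549, 622 to 1062 for both siRNAs in H358, 3.6e+02 to 707 for the same way in both lines, 222 to 366 for reversed by overexpression and 815 to 1292 for knockdown in both lines, with fewer libraries by construction (3.6e+02 is given to 2 digits here and above). The ranges for lists were 17 to 21 in A549, 24 to 26 in H358 and 13 to 14 in overexpression. Libraries that moved a count by over 1.5 times are named beside that count in the report.

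The labels give the groups the same replicate numbers. With the replicate number as a block (replicate block), the counts were 4530 for A549 knockdown, 3573 for siRNA 34 in A549, 4107 for siRNA 36 in A549, 3298 for H358 knockdown, 3320 for siRNA 34 in H358, 1992 for siRNA 36 in H358, 3386 for overexpression, 1384 for the siRNA difference in A549, 374 for the siRNA difference in H358, 3410 for the difference between the lines, 2182 for both siRNAs in A549, 1552 for both siRNAs in H358, 800 for the same way in both lines, 484 for reversed by overexpression and 932 for knockdown in both lines, and 19, 27 and 13 lists were called. The higher share of the 800 was 49.1%, against 51%. On overexpression, histones lost the call with the block (camera adjusted p = 0.073). Differences between replicates 1 and 2 correlated between siCtrl and siEML4-34 with r = 0.29 in A549 and 0.21 in H358. Between siCtrl and siEML4-36 r was -0.074 and -0.048, and between the EML4 siRNAs -0.036 and -0.019. On overexpression r was 0.087. The numbers thus did not pair all groups, and whether they pair siCtrl with siEML4-34 cannot be told from these values.

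Of 1527 values of 192 named genes and comparisons under the alternatives, 1523 kept their direction and side of the threshold, 4 kept direction alone and 0 reversed; of 1018 with 1 library left out, 30 lost the call and 0 reversed. The EML4 difference between siRNAs in A549 lost it in limma-voom (adjusted p = 0.096) and with the experiment alone (adjusted p = 0.07 in edgeR). Of simulated 1.5-fold changes, placed in genes at 5 CPM or more in the control, the smallest share called was 87.7%, on overexpression.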

Other observations

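Overexpression moved cell-shape genes in both directions in lists that did not pass as a whole. EVL, an actin polymerase cofactor (0.89), and WASF3, an activator of actin branching (0.69), rose, while MYO10, the filopodial myosin (-0.52), and BAIAP2 (-0.3) fell. The WASF3 call was lost without oeCtrl replicate 1 (adjusted p = 0.21 in edgeR) or 2 (0.25), without oeEML4 replicate 1 (0.13) or 2 (0.33), in DESeq2 (0.11) and under RLE scaling (0.05). Of mesenchymal genes, the receptor gene AXL (0.81) rose and SNAI2 (-0.59) and S100A4 (-0.58) fell. The growth factor genes AREG (-0.85) and EREG (-0.68) fell, and F3, which encodes tissue factor, fell (-0.74) while ANKRD1 rose (0.65) among YAP targets.

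Among m6A genes, the RNA-binding protein genes IGF2BP1 (0.63) and IGF2BP3 (0.29) rose and the methyltransferase genes METTL14 (-0.28) and METTL3 (-0.25) fell on overexpression. On knockdown, YTHDF3 rose in A549 (0.31) and H358 (0.33), and IGF2BP1 fell in A549 (-0.27) and IGF2BP2 in H358 (-0.2). Calls were lost for IGF2BP3 without oeCtrl replicate 2 (adjusted p = 0.25 in edgeR) or oeEML4 replicate 1 (0.079), for METTL14 without oeCtrl replicate 1 (0.14) or oeEML4 replicate 1 (0.1), and for IGF2BP2 without H358 siCtrl replicate 1 (0.1). YTHDF3 holds GACGTA and IGF2BP3 holds GACAGTA in the 3′ UTR.

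The word GTCGAAA in the 3′ UTR went with lower levels under siRNA 36, with z = -8.42 in A549 and -5.66 in H358, beyond the permuted ranges (5.38 and 5.63), and with z = -0.78 and -1.2 under siRNA 34. In the difference between the siRNAs (34 minus 36) the word had z = 11.08 in A549 and 6.37 in H358, beyond the permuted ranges (5.11 and 5.78). EML4 in A549 lay at 33.1 CPM with siRNA 34 and 38.9 CPM with siRNA 36. These values argue against loss of EML4 as the cause of the word's pattern in A549. This test was chosen after its result was seen, and no other explanation was tested. A549 knockdown and H358 overexpression changed 556 genes in the same direction and 511 in opposite directions. The mitochondrial share of counts was 3.57 ± 0.074% in the overexpression control, against 6.66 ± 0.34% in the H358 siRNA control and 8.97 ± 1% in the A549 control.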
